A study of Homo sapiens with 12 samples.

How the data were processed

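Total RNA was sequenced in 12 libraries of SVG-A cells, 3 each for mock washout and for 2, 4 and 24 h after removal of the gamma-secretase inhibitor. Per the labels, 400000 cells per well were plated on JAG1-Fc and poly-D-lysine with 100 nM Compound E for 18 h and washed 3 times with medium, and libraries were made from 500 ng of RNA (RIN above 8) with a stranded total RNA kit after depletion of ribosomal RNA. The authors aligned reads to hg38 with STAR 2.7.3a, counted them per gene with featureCounts and tested them with DESeq2; the annotation release and the strand setting are not given in the sources used here. The deposited count table holds raw counts per gene and library for 60662 genes, of which 43030 have a count. The authors' deposited table of differential expression holds log2 fold changes and adjusted p-values (p_value) for 1770 genes. Spike-in RNA was added in proportion to cell number per the labels, but the count table holds 0 spike-in genes, so scaling by spike-ins and total RNA per spike-in were not analysed here, and changes are relative to the rest of the RNA. The 37 mitochondrial genes are listed at 0 in every library.

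Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 21677, of them 13517 protein coding, and libraries were scaled by TMM (factors 0.970 to 1.05). Group means were fitted to all 12 libraries (8 residual degrees of freedom) with robust quasi-likelihood dispersion, and each contrast was tested two-sided with Benjamini-Hochberg adjustment at 0.05. The contrasts were 2, 4 and 24 h against mock washout, 4 h against 2 h, 24 h against 4 h, and an F test on the first 3 together. CPM are TMM-scaled, and errors of CPM are SD over 3 libraries. Positions are from GENCODE release 29, found for 21395 of the tested genes. Depth ran from 31.3 to 43.8 M (mega) counts per library, with group means of 40.5 ± 4.06, 37.6 ± 2.12, 36.7 ± 1.71 and 34.2 ± 3.64 M (SD, n = 3) for mock washout, 2, 4 and 24 h. The biological coefficient of variation was 8.88%. Ratios for genes with 1 to 3 counts in a group carry a 95% interval for counting error only.

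Before the data were examined, the comparisons, the alternatives, 31 gene lists (655 entries, 551 tested) and the rule for named genes were fixed. The rule takes, per time against mock washout, the 12 largest rises and 8 largest falls among called genes whose 3 libraries all lie on one side of the 3 mock libraries and whose higher group averages at least 1 CPM, passing over clone-style names. It takes 5 in each direction for the steps between times, every measured canonical Notch target and Notch receptor, and up to 4 members of each other list with the smallest p; some genes that it takes are not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, for the 27 lists with at least 5 measured members, with adjustment over 81 tests against mock washout and over 54 tests between times. Members were counted over all genes tested and adjusted over the list alone.

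Alternatives were DESeq2 size factors in edgeR, library sizes only, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, the replicate number as a block, an adjusted p below 0.01, a change of at least 2-fold, and leaving out each library. A refit of protein-coding genes was added after seeing the data. The fit was tested on simulated data: of genes changed 1.5-fold, 2-fold and 4-fold, 40.3%, 65.7% and 87.9% were called at 2 h, and 4.44% of calls were false. At 4 and 24 h the shares for 2-fold were 61.2% and 61.2%, and false calls 6.49% and 4.35%. At each time the simulation changed 67, 67 and 66 genes by these folds, far fewer than the 6145 called at 24 h. Its share of false calls need not hold there. Figures were drawn with matplotlib 3.10.9.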

Results

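Gene expression was measured by total RNA sequencing in SVG-A cells, a line of human fetal glial cells immortalised with a viral T antigen. The cells were kept for 18 h on plates coated with JAG1-Fc, the extracellular part of the Notch ligand JAGGED1 joined to an antibody Fc tail, in medium with 100 nM Compound E. Compound E inhibits gamma-secretase, the protease that makes the last cut in ligand-bound Notch receptors and so releases their active intracellular part. Removing the inhibitor by 3 washes lets Notch signalling start at a known moment, and cells were harvested 2, 4 and 24 h later. The reference was a mock washout in which the inhibitor was kept and the cells were harvested at once (0 h). The question is which genes respond to Notch activation and when. Each of the 4 groups holds 3 libraries, 12 in all, with 31.3 to 43.8 M (mega) counts per library and 30311 to 31239 genes with a count. Levels below are counts scaled to a common library size (CPM) as mean ± SD over n = 3 libraries, changes are log2 fold changes (LFC) with their standard errors (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 21677 genes. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Because the mock libraries were harvested at once, washing, fresh medium and time in culture accompany inhibitor removal at every time.

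**Figure D1:**
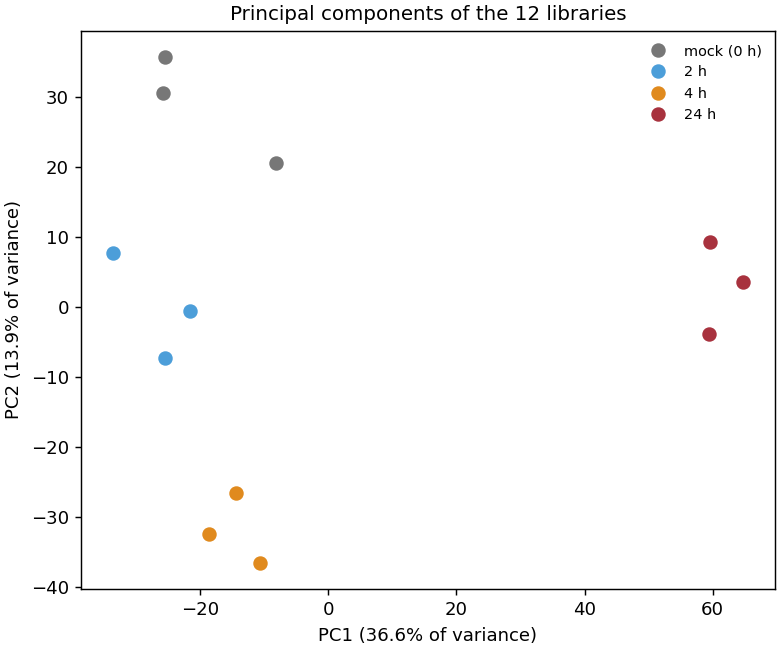
First and second principal components of log2 CPM for the 12 libraries, one point per library and one colour per group. The 3 libraries of 24 h lie at 59.4 to 64.8 on the first component, and the other 9 lie between -33.6 and -8.15.

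Across the whole course, 7534 genes changed at any time against mock washout. The number grew with time, from 393 genes at 2 h to 1866 at 4 h and 6145 at 24 h, and the direction moved from almost entirely upward to evenly mixed. At 2 h 92.6% of the changed genes were higher, at 4 h 60.1% and at 24 h 44.8%. The first principal component held 36.6% of the variance and separated the 24 h libraries from all others, and the second held 13.9%.

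**Figure D2:**
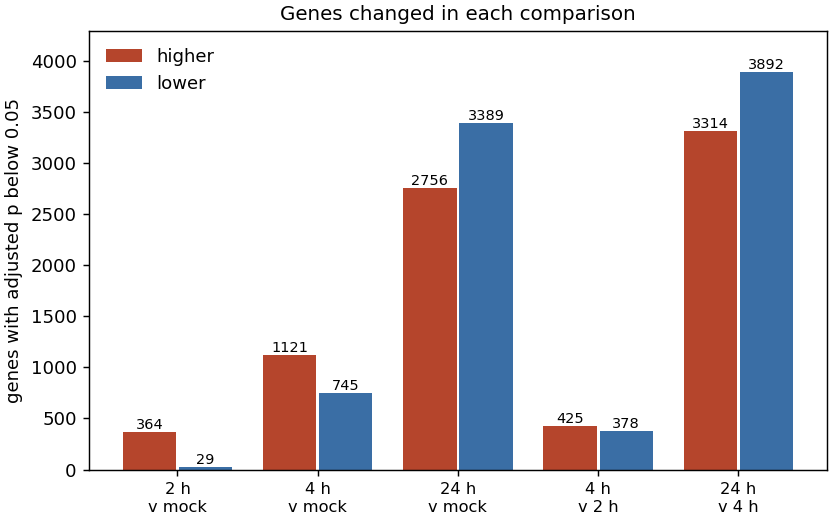
Number of genes higher (red) and lower (blue) in each comparison at an adjusted p below 0.05, from edgeR, with the counts printed above the bars. At 2 h 364 genes were higher and 29 lower, and at 24 h 2756 were higher and 3389 lower.

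Of 9 canonical transcriptional targets of Notch, 5 were higher at 2 h and 8 at 4 h. HES1, the prototype repressor induced by the Notch intracellular domain, stood at 9.23 ± 1.11 CPM in mock washout and at 98.3 ± 17.5 at 2 h, 61.2 ± 12.4 at 4 h and 45.6 ± 6.56 at 24 h (LFC 3.41 ± 0.20, 2.72 ± 0.19 and 2.30 ± 0.19, SE). The gene lies on chromosome 3 from 194136145 to 194138732 on the plus strand (GRCh38). NRARP, a feedback inhibitor of the Notch complex, and HEY1, a repressor of the HES family, peaked at 4 h, where NRARP had risen 9.99-fold to 5.48 ± 0.355 CPM and HEY1 6.03-fold to 6.60 ± 0.456. LFNG, a glycosyltransferase that modifies Notch receptors, was 3-fold higher at 2 and 4 h (26.4 ± 3.43 and 26.2 ± 0.440 CPM against 8.80 ± 1.49) and below mock at 24 h (5.45 ± 0.698, LFC -0.68, adjusted p = 5.17e-04). NOTCH3 rose later and was highest at 24 h: its LFC was 0.65 at 2 h (adjusted p = 0.551), 2.52 at 4 h and 6.53 at 24 h, where it reached 58.9 ± 12.0 CPM from 0.639 ± 0.151.

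Of the 9 measured members of the canonical Notch target list, 5 rose and none fell at 2 h, 8 rose at 4 h, and 7 rose and LFNG fell at 24 h. Adjusted over the list alone, the counts were 6, 8, and 7 higher with 2 lower. Camera placed the list above other genes at each time (adjusted p = 1.67e-11, 5.30e-14 and 7.30e-05), and the call held at all 3 times with an estimated correlation (adjusted p = 0.00479, 0.00412 and 0.0419). HES7, with LFC of -0.50, -0.31 and -0.74, passed the test over all genes at no time and is, with LFNG, 1 of the 2 lower at 24 h over the list alone. Among the receptors, NOTCH2, the most abundant at 555 ± 11.9 CPM in mock washout, fell by 0.24 on the log2 scale at 24 h, and NOTCH1 did not pass the test (LFC 0.17, 0.53 and 0.20). Some calls of targets were lost when 1 library was left out: NRARP at 2 h was not called without 2 h replicate 2 (adjusted p = 0.0525), HEY2 at 4 h without mock replicate 2 (0.0542) and HEY2 at 24 h without mock replicate 2 or 24 h replicate 1 (0.069 and 0.07), and HEYL at 2 h (adjusted p = 0.0486) was lost when any 1 of the 6 libraries was left out (0.0614 to 0.316). With only the 6 libraries compared, NRARP and HEYL were not called at 2 h (adjusted p = 0.0647 and 0.241).

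**Figure D3:**
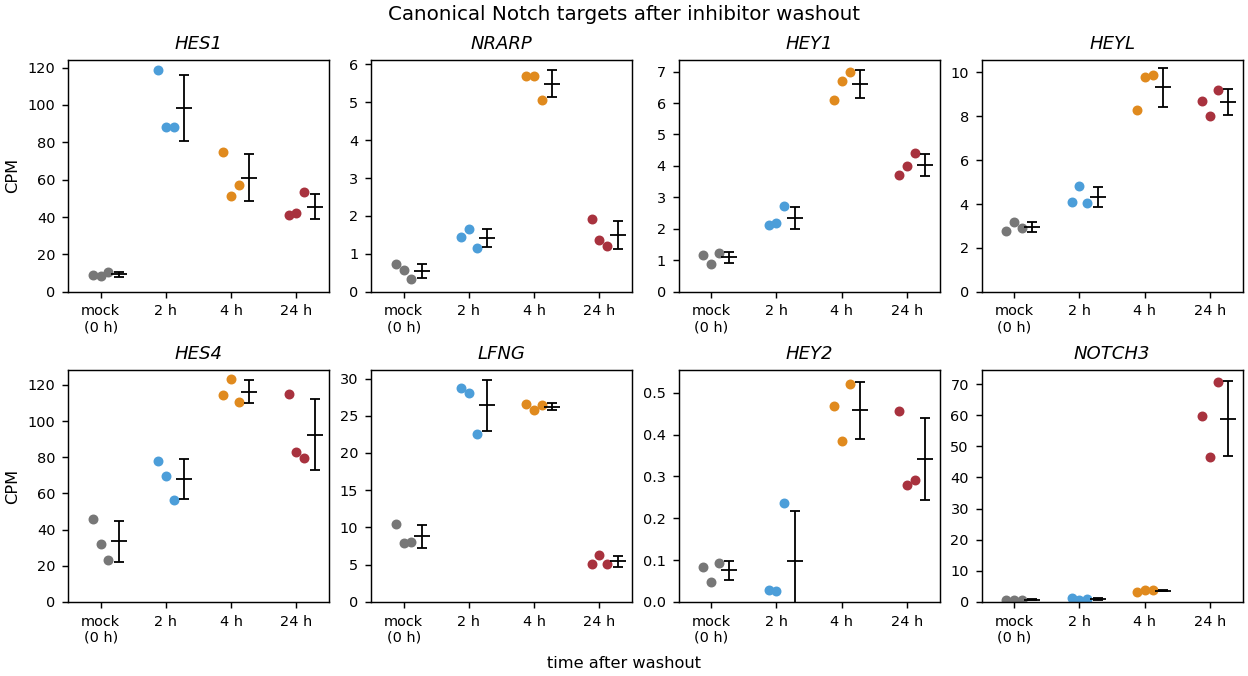
CPM of 8 canonical Notch targets in every library, on linear axes from 0, with a bar for mean and SD (n = 3) beside the 3 points of each group. HES1 is highest at 2 h (98.3 CPM), NRARP and HEY1 at 4 h (5.48 and 6.60 CPM) and NOTCH3 at 24 h (58.9 CPM).

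At 2 h, SNAI2, which encodes a repressor that drives epithelial-mesenchymal transition, rose 16.8-fold from 0.576 ± 0.0822 to 9.67 ± 3.28 CPM (LFC 4.07 ± 0.25, adjusted p = 5.59e-08). Its relative SNAI1 rose from 5.33 ± 0.219 to 25.5 ± 2.44 CPM (LFC 2.26 ± 0.11). The transglutaminase gene TGM5 had an LFC of 4.72 ± 0.58 at a low level (0.0436 ± 0.0423 against 1.18 ± 0.597 CPM). Other genes with large rises that averaged at least 1 CPM were CSF2, which encodes the cytokine GM-CSF (LFC 3.70), the forkhead factor gene FOXS1 (3.58), SH2D3C (3.34), GGT5 (2.85), AACSP1 (2.78), TRIB1 (2.73), RAB7B (2.65) and DUSP5, a phosphatase that restrains ERK (2.57). JAG1, the gene of the ligand itself, rose from 24.8 ± 1.95 to 90.3 ± 16.4 CPM (LFC 1.86), and SOX9, a glial and progenitor transcription factor, from 11.3 ± 0.720 to 44.7 ± 6.35 (LFC 1.99).

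Falls at 2 h were few and small. NEAT1, a nuclear long noncoding RNA, fell from 521 ± 43.4 to 289 ± 21.5 CPM (LFC -0.85, adjusted p = 5.50e-05). It belongs to a list of RNAs that track RNA quality, too small to test, of which it alone of 4 measured was lower at 2 and 4 h (1 and 2 lower adjusted over the list alone). SOCS3, an inhibitor of cytokine signalling, fell from 30.7 ± 4.24 to 16.7 ± 4.56 CPM (LFC -0.88), and ADAMTS1 from 61.2 ± 8.85 to 40.1 ± 1.98 (LFC -0.61). ADM, PNRC1, SKIDA1, MED15P9 and RPL17P19 also fell (LFC -0.84, -0.63, -0.62, -0.90 and -1.17). SKIDA1 and MED15P9 overlap a gene on the opposite strand, and RPL17P19 lies inside ADGRL3 on the same strand. In all, 393 genes changed, 364 higher and 29 lower, of which 145 and 1 changed at least 2-fold. The number lower was unstable. It was 10 without 2 h replicate 2, 18 without 2 h replicate 1 and 14 with only the 6 libraries compared. It was 55 with DESeq2, 69 with the replicate number as a block and 99 with no filter. EGR1 (LFC 2.87 ± 0.57, adjusted p = 0.0448) lost its call when any 1 of the 6 libraries was left out (adjusted p 0.107 to 0.192), PNRC1, SKIDA1 and RPL17P19 with any of 5, MED15P9 with any of 4 and ADM with 1, 2 h replicate 2 (0.083). With only the 6 libraries compared, SOCS3 (adjusted p = 0.0806), MED15P9 (0.063), SKIDA1 (0.123) and RPL17P19 (0.144) were not called.

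Several lists of signal-responsive genes rose together at 2 h. Of 27 immediate-early genes, which respond to stimuli without new protein synthesis, 14 rose and none fell (21 higher and 1 lower adjusted over the list alone), among them TRIB1 (6.33 ± 0.727 to 42.1 ± 5.18 CPM), DUSP5 (32.1 ± 3.30 to 191 ± 15.3), CSRNP1 (LFC 1.27) and MCL1 (0.55). In the list of NF-κB targets and cytokines 7 of 18 rose (12 adjusted over the list alone), led by CSF2, IL6 (LFC 2.01), IL1B (1.89) and VCAM1 (1.68). Of 26 further genes reported as Notch targets in particular cell types, 10 rose (10 adjusted over the list alone), including SNAI2, SNAI1, SOX9 and CCND1 (LFC 1.13), and of 11 glucocorticoid targets 4 rose (5 adjusted over the list alone), DUSP1 (1.61), KLF9 (1.02), CRISPLD2 (0.68) and ERRFI1 (0.54). Camera called these 4 lists higher (adjusted p = 2.44e-28, 5.72e-14, 5.72e-14 and 4.23e-07), and with an estimated correlation the adjusted p was 0.00479, 0.0187, 0.00412 and 0.00818.

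The YAP/TEAD target list also rose at 2 h by the preset test, with 8 of 17 higher (12 adjusted over the list alone), led by ANKRD1 (15.2 ± 1.79 to 82.1 ± 23.9 CPM) and CCN2 (107 ± 18.8 to 412 ± 14.8). In the TGF-β and BMP list 5 of 18 rose (8 higher and 1 lower adjusted over the list alone), including PMEPA1 (LFC 0.63) and ID3 (1.33), the latter not called without mock replicate 2 (adjusted p = 0.0506). Both calls (adjusted p = 7.17e-16 and 2.78e-06) were lost with an estimated correlation (adjusted p = 0.0704 and 0.19). The remaining calls at 2 h rested on small shifts of the whole list, with medians of 0.14 for ribosome biogenesis, 0.09 for ATF4 targets and 0.16 for contractile genes upward and -0.07 for G2/M genes downward, and each was lost with an estimated correlation (adjusted p = 0.496, 0.698, 0.415 and 0.624). Leaving out 1 library also ended the calls of ATF4 targets (without mock replicate 1 or 2 or 2 h replicate 3, adjusted p = 0.139, 0.392 and 0.809), contractile genes (without mock replicate 2, 0.0531) and G2/M genes (without 2 h replicate 1, 0.196).

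**Figure D4:**
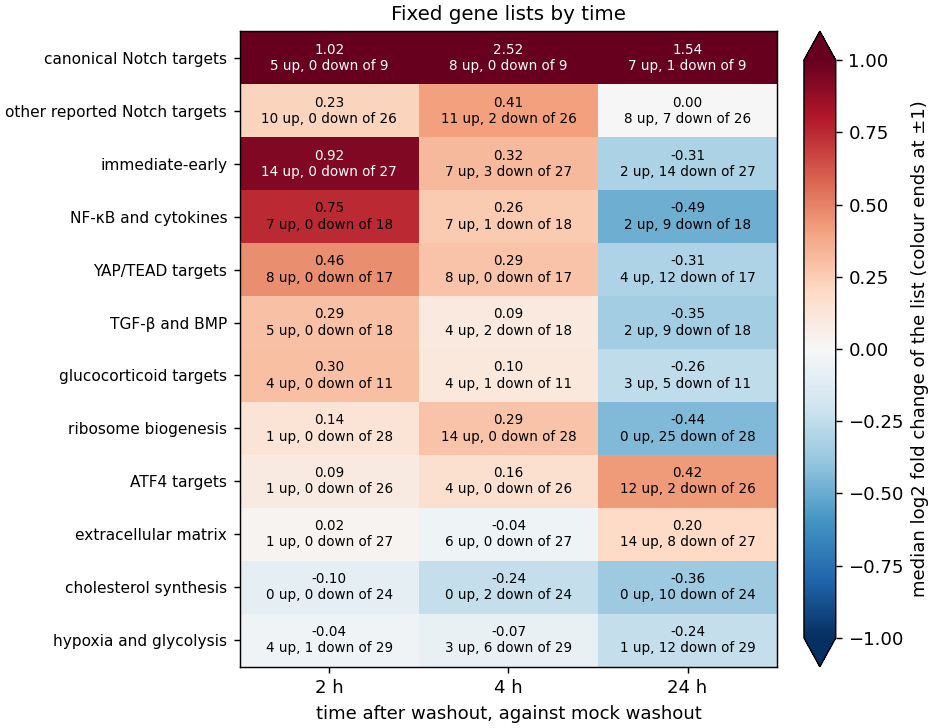
Median LFC against mock washout of 12 gene lists fixed in advance, at 2, 4 and 24 h; each cell prints the median and how many measured members were higher or lower at an adjusted p below 0.05. The immediate-early list goes from 14 of 27 higher at 2 h to 14 of 27 lower at 24 h, and canonical Notch targets go from 5 of 9 higher to 7 of 9, with LFNG among those higher at 2 h but lower at 24 h.

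At 4 h several of the genes that led at 2 h stood higher still, and genes not called at 2 h joined them. SNAI2 reached 22.8 ± 1.27 CPM (LFC 5.30 ± 0.24), TGM5 3.78 ± 0.372 (6.39), SH2D3C 13.3 ± 2.11 (5.54), FOXS1 7.83 ± 1.24 (4.86) and JAG1 229 ± 10.5 (3.20 ± 0.12, adjusted p = 1.25e-09). Genes at or near the detection limit in mock washout included SLC6A12, a transporter of betaine and GABA (0.106 ± 0.0751 to 5.34 ± 0.706 CPM, LFC 5.58 ± 0.32), the keratin gene KRT3 (0.0439 ± 0.0350 to 2.95 ± 0.548, LFC 6.03) and GUCY1B1, a subunit of the nitric oxide receptor guanylyl cyclase (LFC 4.10). COL5A3, a chain of type V collagen, rose from 1.45 ± 0.463 to 31.4 ± 4.68 CPM (LFC 4.44), and ABCA1, the cholesterol efflux transporter, from 0.702 ± 0.187 to 11.9 ± 0.600 (LFC 4.07).

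SLC6A12 (chromosome 12, 190077 to 214570, minus strand, GRCh38) lies beside IQSEC3 (66765 to 178460, plus strand) and the noncoding IQSEC3-AS1 (166856 to 182399, minus strand), and all 3 rose strongly at 4 h. IQSEC3 rose from 0.0610 ± 0.0460 to 1.05 ± 0.276 CPM (LFC 4.08, adjusted p = 8.63e-06). IQSEC3-AS1 had 2 counts over the 3 mock libraries and 3.60 ± 0.580 CPM at 4 h, a ratio between 59.1 and 1780 (95% interval for counting error only). The pseudogene SDHCP1 had 1 count in mock washout and 1.06 ± 0.289 CPM at 4 h, a ratio between 22.7 and 5140. IQSEC3-AS1 overlaps IQSEC3 on the opposite strand and SDHCP1 lies inside CCDC102B on the same strand. The strand setting of the counting is not given in the sources used here, so reads of such overlapping genes cannot be told apart. IQSEC3-AS1 also lies downstream of SLC6A12 on the same strand. Whether transcripts running on from SLC6A12 gave counts at IQSEC3-AS1 and IQSEC3 was not tested.

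Large falls at 4 h included SOCS3 (30.7 ± 4.24 to 7.74 ± 0.213 CPM, LFC -1.99 ± 0.16), ADM, which encodes the vasodilator peptide adrenomedullin (6.28 ± 0.222 to 1.68 ± 0.228, LFC -1.90), and BDNF, a neurotrophin (37.2 ± 2.68 to 12.9 ± 1.48, LFC -1.53, adjusted p = 1.14e-09), which overlaps the antisense gene BDNF-AS. The small or pseudogene RNAs RN7SL381P, SMYD3-IT1, RNU6-1283P and RPL9P16 fell as well (LFC -1.97, -1.87, -1.83 and -1.82), each of which lies inside a larger gene on the same strand. In all, 1121 genes were higher and 745 lower, 349 and 87 of them at least 2-fold. Without 4 h replicate 2, 411 were lower, and with the replicate number as a block 1159. HGF (LFC -1.65, adjusted p = 0.0264) lost its call without mock replicate 2 (LFC -1.20) or without any 1 of the 3 libraries of 4 h (adjusted p 0.0522 to 0.166 over the 4 fits).

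Among the lists at 4 h, the further reported Notch targets had 11 of 26 higher and 2 lower (16 and 2 adjusted over the list alone), among them SNAI2, JAG1, SNAI1 (34.0 ± 2.48 CPM) and SOX9 (54.4 ± 1.71). Its call held with an estimated correlation (adjusted p = 8.50e-10 and 0.00639). Ribosome biogenesis genes rose in number: 14 of 28 were higher and none lower (19 adjusted over the list alone), among them RCL1 (LFC 0.68), RRS1 (0.61), POLR1B (0.47) and NOLC1 (0.40). The immediate-early list had 7 higher and 3 lower, with TRIB1 at 73.5 ± 7.85 CPM and ZFP36 lower (LFC -0.83); YAP/TEAD targets had 8 of 17 higher, with ANKRD1 at 190 ± 18.9 CPM; NF-κB targets and cytokines had 7 higher and 1 lower, with VCAM1 (LFC 2.81) and IL1B (2.60) in front. Adjusted over the list alone these 3 counts were 10 and 5, 11 and 2, and 8 and 2.

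With an estimated correlation the calls of ribosome biogenesis (adjusted p = 1.47e-11 with the preset correlation), immediate-early (0.0315), YAP/TEAD (3.67e-05) and NF-κB (0.00341) genes at 4 h were lost (adjusted p = 0.415, 0.508, 0.415 and 0.415). Of 11 glucocorticoid targets 4 rose, led by SGK1 (24.3 ± 0.713 to 106 ± 26.5 CPM), and 1 fell (4 and 1 adjusted over the list alone), a call (adjusted p = 0.0116) also lost (0.166). Of 26 ATF4 targets 4 rose (4 higher and 1 lower adjusted over the list alone), including CEBPB (LFC 1.72), and of 7 epithelial genes KRT18 (LFC 1.41) and KRT5 (1.18) rose (2 adjusted over the list alone). These calls (adjusted p = 0.00896 and 0.0424) were lost with an estimated correlation (adjusted p = 0.698 and 0.269). KRT5 was not called without mock replicate 1 or 4 h replicate 1 (adjusted p = 0.0875 and 0.112), and the epithelial list not without mock replicate 2, 4 h replicate 1 or 3 or any library of 24 h (0.0509 to 0.314). The calls of ATF4 targets (without mock replicate 1 or 2 or 4 h replicate 3, adjusted p 0.0509 to 0.197) and immediate-early genes (without mock replicate 2 or 3, 4 h replicate 1 or 24 h replicate 2 or 3, 0.0501 to 0.146) ended in the same way.

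In the lists that camera called lower at 4 h, few members passed the test. No replication histone gene of 29 passed the test alone or adjusted over the list alone, although the list's median was -0.80 (adjusted p = 1.47e-11, and 0.442 with an estimated correlation). Of 24 cholesterol genes 2 were called lower, SREBF2 (LFC -0.20) among them, and 2 adjusted over the list alone (list adjusted p = 0.00143, and 0.698 with an estimated correlation). In the hypoxia and glycolysis list ADM, SLC2A3 (LFC -0.91) and 4 others of 29 fell while HK2 (0.62), PFKFB3 (0.57) and ANGPTL4 (3.53) rose, with the same counts adjusted over the list alone (list adjusted p = 0.0461, and 0.453 with an estimated correlation). Of 36 G2/M genes 3 fell, BUB1, CKS2 and CDC25C, and 10 adjusted over the list alone (list adjusted p = 4.52e-05, and 0.608 with an estimated correlation). SREBF2, BUB1, CKS2 and CDC25C each lost their calls in 4 to 6 of the 6 fits that left out 1 library (adjusted p 0.101 to 0.275, 0.0666 to 0.137, 0.0503 to 0.154 and 0.0828 to 0.155). The cholesterol list lost its call without mock replicate 3 (adjusted p = 0.361), and the hypoxia and glycolysis list in 8 of the 12 such fits (0.0517 to 0.288).

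At 24 h large rises were seen in genes that had been at low levels in mock washout. SLC6A12 reached 39.3 ± 5.04 CPM (LFC 8.46 ± 0.28, adjusted p = 1.22e-12), COL5A3 126 ± 13.7 (6.44 ± 0.21), GUCY1B1 9.07 ± 2.52 (6.85) and its partner subunit GUCY1A1 2.29 ± 1.10 (5.68). NOTCH3, which encodes a receptor typical of mural cells, rose 92.4-fold, COL26A1 78-fold to 2.85 ± 0.476 CPM, SEMA5B 67.8-fold to 3.62 ± 0.670 and GGT5 51.2-fold to 15.9 ± 0.856. IQSEC3-AS1 (6.04 ± 0.103 CPM), TMC3 (3.16 ± 0.770), FMOD, which encodes the collagen-binding fibromodulin (1.07 ± 0.392), and PLA2G5 (1.17 ± 0.678) had 2, 3, 1 and 2 counts over the mock libraries, giving ratios between 99.9 and 3000, 43.6 and 626, 23.2 and 5250, and 18.9 and 584 (95% intervals for counting error only). TMC3 overlaps antisense genes.

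Large falls at 24 h included WNT7B, a Wnt ligand, from 8.96 ± 1.78 to 0.504 ± 0.0617 CPM (LFC -4.13 ± 0.22, adjusted p = 3.75e-11). MYPN (LFC -4.28), MPP4 (-4.17), the metalloproteinase gene MMP3 (-4.26), the cytokine gene IL24 (-4.04), ARL14 (-3.76) and the antisense transcript C12orf75-AS1 (-4.86) fell to below 1 CPM. C12orf75-AS1 and MMP3 overlap genes on the opposite strand. In all, 2756 genes were higher and 3389 lower, 617 and 685 at least 2-fold. The balance of directions depended on scaling: with library sizes only, 3918 were higher and 2513 lower, 60.9% higher against 44.8%, and the median LFC of all genes was 0.051 against -0.022.

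Of the lists called higher at 2 h, the immediate-early, YAP/TEAD, NF-κB and TGF-β lists were called lower at 24 h. So was the ribosome biogenesis list. The canonical Notch and ATF4 lists were called higher at both times. With an estimated correlation the ribosome biogenesis (adjusted p = 0.496 and 0.415) and ATF4 calls (adjusted p = 0.698 and 0.698) were lost at 2 and 24 h. The further reported Notch targets, glucocorticoid targets and contractile genes had no call at 24 h (adjusted p = 0.952, 0.547 and 0.547). Of 27 immediate-early genes 14 fell, among them FOSL1 (50.5 ± 4.08 to 7.40 ± 0.965 CPM), PLAUR (42.4 ± 4.59 to 8.01 ± 1.17), JUN (LFC -1.67) and ATF3 (-1.25), and 2 rose, DUSP5 (0.42) among them. Of 17 YAP/TEAD targets 12 fell, including NT5E (64.2 ± 3.69 to 8.05 ± 0.558 CPM), AXL (1620 ± 59.7 to 631 ± 64.0) and DLC1 (LFC -0.96), and 4 rose, ARHGEF17 (0.58) among them. NF-κB targets and cytokines had 9 of 18 lower (BIRC3 LFC -2.36, LIF -1.28) and 2 higher, VCAM1 (1.89) and CCL2 (1.20), and the TGF-β and BMP list 9 of 18 lower (ATOH8 LFC -1.40) and 2 higher, ID4 (0.44) among them. Adjusted over the list alone the higher and lower counts were 3 and 15, 4 and 12, 2 and 11, and 2 and 10. Camera called these 4 lists lower (adjusted p = 0.00106, 0.00267, 0.0034 and 0.00337), and all 4 calls were lost with an estimated correlation (adjusted p = 0.415, 0.505, 0.415 and 0.415).

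Genes of biosynthesis and metabolism also moved at 24 h. Ribosome biogenesis genes, of which 14 had been higher at 4 h (list call lost with an estimated correlation, adjusted p = 0.415), were lower in 25 of 28 members and higher in none (26 adjusted over the list alone), including WDR43 (184 ± 17.6 to 112 ± 8.31 CPM), RRS1 (LFC -0.69), PNO1 (-0.60) and TSR1 (-0.54). Of 24 cholesterol synthesis genes 10 fell (13 adjusted over the list alone), FDFT1 (LFC -0.56) among them, but only 4 with library sizes only. FDFT1 was not called without 24 h replicate 1 (adjusted p = 0.051), nor the cholesterol list without mock replicate 3 (0.125). Of 29 hypoxia and glycolysis genes 12 fell and 1 rose (the same adjusted over the list alone), with ENO1 (2990 ± 134 to 2080 ± 143 CPM), PFKP (LFC -0.79) and HK2 (-0.73) lower. ATF4 targets went up, 12 of 26 higher and 2 lower (13 and 2 adjusted over the list alone), with NUPR1 (LFC 2.37), SHMT2 (LFC 0.68) and the serine synthesis enzyme gene PHGDH (122 ± 25.6 to 288 ± 18.5 CPM). S phase genes had 13 of 34 higher and 3 lower (15 and 4 adjusted over the list alone), including the replicative helicase genes MCM6 (LFC 0.60), MCM3 (0.45) and MCM5 (0.38).

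These 5 calls (adjusted p = 1.48e-10, 0.0034, 0.00267, 0.00267 and 0.0113, in that order) were all lost with an estimated correlation (adjusted p = 0.415, 0.698, 0.328, 0.698 and 0.542). The further reported Notch targets split at 24 h, with 8 of 26 higher and 7 lower (the same adjusted over the list alone) and no list call (adjusted p = 0.952). JAG1 (124 ± 7.74 CPM), SNAI2 (4.89 ± 0.592), SNAI1 (LFC 0.93) and PDGFRB, a receptor of mural cells (85.9 ± 17.8 to 618 ± 16.8), were higher, and NT5E, CCND1 (LFC -1.63) and CDKN1A (-0.94) were lower.

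**Figure D5:**
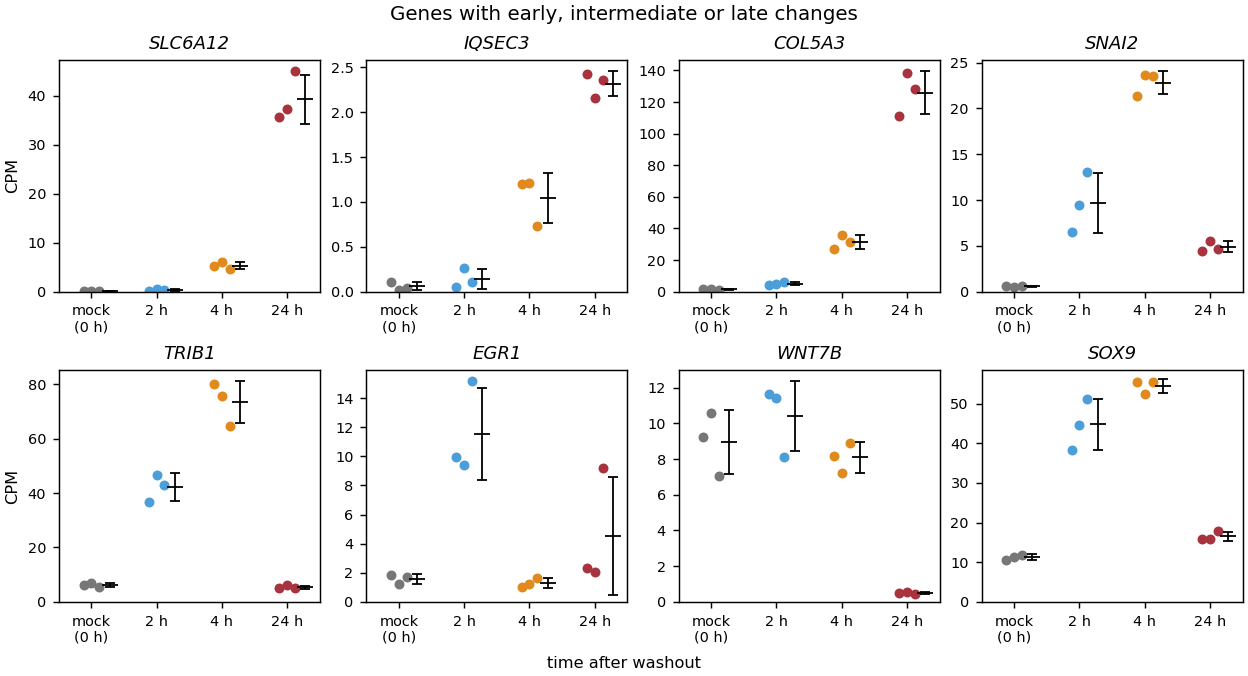
CPM of 8 genes in every library, on linear axes from 0, with a bar for mean and SD (n = 3). SLC6A12, IQSEC3 and COL5A3 are highest at 24 h (39.3, 2.32 and 126 CPM), SNAI2, TRIB1 and SOX9 at 4 h (22.8, 73.5 and 54.4 CPM) and EGR1 at 2 h (11.5 CPM), and WNT7B falls to 0.504 CPM at 24 h.

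Between 2 and 4 h, 803 genes changed, 425 higher and 378 lower. Of the 364 genes higher at 2 h, more rose further (124) than fell (50). SLC6A12 rose 16.7-fold (LFC 4.06 ± 0.27, adjusted p = 1.92e-07), IQSEC3 7.08-fold, GUCY1B1 6.39-fold, COL5A3 6.10-fold and CCDC102B 5.86-fold, from 2.55 ± 0.818 to 15.0 ± 2.32 CPM. CCDC102B and NEDD9 overlap a gene on the opposite strand. NRARP (LFC 1.95), NOTCH3 (1.87), HEY1 (1.49) and HEYL (1.11) rose further, while HES1 (LFC -0.69, adjusted p = 0.065) and LFNG (-0.01) did not change past the threshold. NEDD9, which encodes a focal adhesion scaffold, fell from 18.5 ± 0.891 to 5.61 ± 0.995 CPM (LFC -1.72), and RNU6-1283P and RPL9P16 fell with LFC of -1.58 and -1.72. The drops of EGR1 (LFC -3.15, adjusted p = 0.0206) and SKOR1 (-2.50, 0.0131) were not called without any 1 of the 3 libraries of 4 h. That of EGR1 was also not called without 2 h replicate 1 or 3, nor that of RPL9P16 without 4 h replicate 2 (0.06). The drops themselves stayed in those fits, with LFC of -2.90 to -3.37 for EGR1, -2.41 to -2.56 for SKOR1 and -1.47 for RPL9P16.

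Immediate-early genes fell between 2 and 4 h in 12 of 27 members, with 1 higher, and canonical Notch targets rose in 4 of 9 with none lower. Adjusted over the list alone, 2 and 18 immediate-early genes were higher and lower, and 6 and 1 canonical targets. The medians were -0.53 and 1.11. Camera called both (adjusted p = 2.95e-12 and 5.67e-07), and both calls were lost with an estimated correlation (adjusted p = 0.0661 and 0.0621). They were among 9 lists called for this step, none of them with an estimated correlation. Replication histones (median -0.70, adjusted p = 2.95e-12), hypoxia and glycolysis (0.0111), cholesterol (0.0227) and YAP/TEAD (0.0485) genes were also called lower. Ribosome biogenesis genes (1.33e-05), further reported Notch targets (0.0227) and epithelial genes (0.0413) were also called higher. The count of 803 genes moved by over 1.5 times when 1 library was left out in 4 cases, to 428 without 4 h replicate 2, 473 without 2 h replicate 1, 515 without 2 h replicate 2 and 523 without 4 h replicate 3.

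Between 4 and 24 h, 7206 genes changed, 3314 higher and 3892 lower. FMOD, PLA2G5, COL26A1, ZNF467 and NOTCH3 were among the large rises. FMOD had 2 counts over the libraries of 4 h, a ratio between 16.2 and 500 (95% interval for counting error only). NOTCH3 rose from 3.65 ± 0.297 to 58.9 ± 12.0 CPM (LFC 4.01 ± 0.17, adjusted p = 5.86e-11), COL26A1 21.7-fold and ZNF467 11.9-fold. RGS4, a regulator of G protein signalling, fell from 61.4 ± 10.6 to 1.95 ± 0.352 CPM (LFC -4.97 ± 0.14, adjusted p = 5.04e-14), WNT7B from 8.09 ± 0.865 to 0.504 ± 0.0617 and TRIB1 from 73.5 ± 7.85 to 5.40 ± 0.565. Of the Notch targets LFNG (LFC -2.26), NRARP (-1.88) and HEY1 (-0.71) fell, and HES1 (-0.42), HES4 (-0.33), HEYL (-0.11) and HEY2 (-0.43) did not pass the test. All 28 ribosome biogenesis genes were lower, as were 14 of 17 YAP/TEAD targets, 18 of 27 immediate-early genes and 12 of 18 NF-κB targets and cytokines, and 11 of 29 replication histone genes and 17 of 34 S phase genes were higher. Adjusted over the list alone the lower counts were 28, 14, 18 and 17, and the higher counts 19 and 17. Camera called these 6 lists (adjusted p = 2.61e-15, 1.94e-07, 2.80e-06, 4.43e-07, 1.11e-07 and 0.0111), none of them with an estimated correlation (adjusted p = 0.339, 0.325, 0.258, 0.163, 0.585 and 0.585). The further reported Notch targets had 15 of 26 lower and 3 higher, TGF-β and BMP genes 11 of 18 lower and 2 higher, and G2/M genes 15 of 36 higher and 3 lower. Camera called these lists too (adjusted p = 6.45e-06, 0.000512 and 0.0303), but not with an estimated correlation (adjusted p = 0.0621, 0.339 and 0.741). With library sizes only, 4430 genes were higher and 3108 lower, 58.8% higher against 46.0%.

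The early response largely carried over to 4 h and then dispersed. Of the 364 genes higher at 2 h, 293 (80.5%) were higher at 4 h and 4 lower, while at 24 h 126 were higher and 123 lower. Independent lists of these sizes would share 18.8 genes higher at 2 and 4 h, and 46.3 higher at 2 and 24 h with 56.9 higher then lower. For 4 and 24 h, 372 genes were higher at both (142.5 for independent lists), 338 lower at both (116.5) and 313 higher then lower (175.3). The 3 comparisons use the same mock libraries, so part of the excess may come from the shared controls. Simulated groups with no effect shared at most 2, 1 and 1 calls in the same direction. That simulation held no changed genes, so it cannot tell how many of the observed shared calls the controls add. Across genes, which are not independent replicates, LFC correlated at 0.648 (2 and 4 h), 0.278 (2 and 24 h) and 0.460 (4 and 24 h), against 0.497, 0.495 and 0.493 in the simulation, with covariances of 0.123, 0.0729 and 0.154 against 0.0439, 0.0440 and 0.0437.

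By time class, 121 genes were higher at all 3 times and 66 at 2 h only. Of the genes higher at 4 h, 828 had not been called at 2 h. From 4 to 24 h 781 genes higher at 4 h fell and 97 rose further, while of the genes lower at 4 h 353 rose and 142 fell further.

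The authors' deposited table of differential expression lists 1770 genes, every one with an adjusted p below 0.001 and a change over 1.5-fold at a time point. In the authors' deposited table SNAI2 has a log2 fold change of 4.07 at 2 h and COL5A3 one of 1.82. Calls in the same direction were shared by the deposited table and the edgeR fit for 297 genes at 2 h, 720 at 4 h and 1613 at 24 h, and 0 went in opposite directions. At an adjusted p below 0.05 the deposited table (DESeq2) had 330 genes higher and 25 lower at 2 h, 502 and 262 at 4 h, and 701 and 920 at 24 h. Both fits use the same counts, so the shared calls are not an independent check.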

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

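The tests of a shared transient response, of washing alone, of library scaling and of time in culture were chosen after the results were seen; the correction for GC content and length was written before its result was seen. The results below moved in opposite directions against mock washout at 4 and 24 h, with the difference between the times tested directly. LFNG, a glycosyltransferase of Notch receptors, had an LFC of 1.58 at 4 h and -0.68 at 24 h, a difference of -2.26 (adjusted p = 1.00e-10, edgeR). RGS4, a regulator of G protein signalling, had an LFC of 2.42 at 4 h and -2.56 at 24 h, a difference of -4.97 (adjusted p = 5.04e-14). The YAP/TEAD list had medians of 0.29 and -0.31, with a median difference of -0.94 (adjusted p = 1.94e-07, camera; adjusted p = 0.325 with an estimated correlation). NF-κB targets and cytokines had medians of 0.26 and -0.49, with a median difference of -0.83 (adjusted p = 4.43e-07; adjusted p = 0.163 with an estimated correlation).

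Immediate-early genes had a median LFC of 0.32 at 4 h and -0.31 at 24 h, with a median difference of -0.76 (adjusted p = 2.80e-06; adjusted p = 0.258 with an estimated correlation), after a rise together with canonical Notch targets at 2 h. If washing had raised both lists alike in 1 transient response, both would fall back between 2 and 4 h. They parted instead: the median change from 2 to 4 h was 1.11 over 9 canonical targets and -0.53 over 27 immediate-early genes. The mean log2 CPM of the canonical list less that of the immediate-early list, taken per library, went from -2.09 ± 0.1 at 2 h to -0.49 ± 0.06 at 4 h (SD, n = 3), a change of 1.6. All 3 libraries of 4 h lay above all 3 of 2 h, and 0.1 is the smallest p that an exact permutation of 6 libraries can give. The lists as sets thus ran unlike courses from 2 to 4 h, by more than the spread between these libraries. Part of the canonical rise in this step came from NOTCH3, which was not called at 2 h (LFC 0.65, adjusted p = 0.551, edgeR). HEY1, called at 2 h (LFC 1.10, adjusted p = 0.0016), rose further. A washing response that ran an unlike course in each list was not tested. A permutation over genes (difference of medians 1.64, p = 0.00011, 100000 permutations) decides nothing further, as it treats members as independent, and both list calls for this step were lost with an estimated correlation (adjusted p = 0.0621 and 0.0661). HES1 (LFC -0.69, adjusted p = 0.065) and LFNG (-0.01) did not rise in this step, so for these targets the test excludes nothing. Whether washing and fresh medium alone raised the immediate-early genes cannot be told apart from Notch activation, since 0 libraries were washed with the inhibitor kept and harvested at 2 h or later. A response of these genes to Notch itself stays open for the same reason.

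Ribosome biogenesis genes had a median LFC of 0.29 at 4 h and -0.44 at 24 h, with a median difference of -0.71 (adjusted p = 2.61e-15; adjusted p = 0.339 with an estimated correlation). The choice between TMM scaling and library sizes only does not account for the fall at 24 h. With library sizes only, 23 of the 28 members were lower and the median was -0.372. That choice shifted the LFC of all genes by a median of only 0.073. Both scalings are relative to the counted RNA, so a change in RNA per cell was not tested. A correction for GC content and exon length left the median at -0.43 from -0.44, with 28 of 28 below 0 and an SD of 0.17 over members. Time in culture cannot be told apart from time since Notch activation, since 0 libraries were kept with the inhibitor and harvested at 24 h. A response to Notch activation is open and untested.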

How the results depend on the processing

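All alternatives below were fixed before the data were examined except the refit of protein-coding genes, and the cause of the shifts was not tested unless given. The number of genes changed at 2 h was 627 with no filter. At an adjusted p below 0.01, the counts were 251 at 2 h, 1119 at 4 h, 4016 at 24 h and 400 between 2 and 4 h, a stricter threshold by construction. With at least a 2-fold change they were 146, 436 and 1302, then 164 between 2 and 4 h, 1422 between 4 and 24 h and 1509 at any time, again by construction. Overlaps at an adjusted p below 0.01 were 194 higher and 8 lower at both 2 and 4 h; 73 higher, 5 lower and 74 higher then lower at 2 and 24 h; and 247, 182 and 162 at 4 and 24 h. With DESeq2, 37 genes were lower at both 2 and 4 h and 9 higher then lower, and 21 lower at both 2 and 24 h. Whether replicate numbers pair the libraries was not settled. Same-number correlations ran from -0.132 to 0.184 (mean 0.0433, 8 of 18 above 0.1), and 8 of the 12 libraries correlated best with their own number. With the number as a block, 565 genes changed at 2 h, 2575 at 4 h and 7040 at 24 h. In that fit 51 genes were lower at both 2 and 4 h and 9 higher then lower. At 2 and 24 h 25 were lower at both and 195 higher then lower, and at 4 and 24 h 513 and 473. List calls against mock washout fell from 34 to 8 with an estimated correlation. Leaving out 1 library gave 264 to 381 genes at 2 h, 1253 to 1698 at 4 h, 4957 to 6463 at 24 h, 428 to 662 between 2 and 4 h, 5863 to 6517 between 4 and 24 h, 6203 to 8109 at any time, and 30 to 35 list calls. Of 7996 values for named genes under alternatives, 7311 kept their direction and side of the threshold, 644 were no longer called, 29 became called and 12 turned direction; of 578 for lists, 511 were kept and 67 no longer called. The 12 were not called in the fit they are set against: HEY2 at 2 h against mock washout (-0.16 with limma-voom, -1.34 without 2 h replicate 3, range -1.34 to 0.82 over libraries left out), NOTCH2 at 2 h against mock washout (0.01 without 2 h replicate 3, range -0.05 to 0.01), HES7 at 4 h against mock washout (0.04 without mock replicate 1, range -0.45 to 0.04), HES7 4 h against 2 h (-0.04 without 2 h replicate 3, range -0.04 to 0.57), LFNG 4 h against 2 h (0 with library sizes only and with limma-voom, 0.06, 0.05 and 0.01 without 2 h replicate 1, 2 h replicate 2 and 4 h replicate 2, range -0.11 to 0.06), and NOTCH2 4 h against 2 h (0.02 and 0 without 2 h replicate 2 and 4 h replicate 2, range -0.04 to 0.02). Scaling by spike-ins was not run, as the table holds 0 spike-in genes. Genes changed 1.5-fold were found in 40.3% of simulated cases at 2 h, so smaller changes can be missed at this depth.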

Other observations

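The neighbour test was planned before its result was seen, except for its 1 kb minimum distance; the microRNA cluster was looked at after the data were seen. Genes of the extracellular matrix and of glial identity, described here from lists fixed in advance, changed in both directions at 24 h. Of 27 matrix genes 14 rose and 8 fell (15 and 8 adjusted over the list alone), with LAMA4, a laminin chain of vessel walls, at 41.5 ± 12.6 CPM from 5.16 ± 0.819 (SD, n = 3) and COL6A1 (LFC 0.60) higher, and the matrix glycoprotein gene TNC (566 ± 40.5 to 116 ± 4.22) and TIMP3 (LFC -1.68) lower. Of 16 astrocyte and neural progenitor genes 5 rose and 6 fell (5 and 7 adjusted over the list alone), with the glutamate transporter gene SLC1A3 (1.85 ± 0.305 to 9.53 ± 1.31 CPM) and PAX6 (9.15 ± 1.37 to 37.2 ± 4.58) higher and CD44 (276 ± 31.9 to 76.3 ± 4.65) and VIM (2730 ± 184 to 1660 ± 75.0) lower. Of the 20 genes fixed for this list, 12 averaged above 1 CPM in mock washout, 9 of them above 10 CPM, with VIM highest. GFAP, S100B, AQP4, SLC1A2, FABP7, NES, SOX2 and HES5 averaged below 1 CPM there, from 0 (S100B) to 0.471 CPM (NES). Of 14 contractile and mural genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), with PDGFRB higher (LFC 2.85) and CSPG4 (-0.96), SMTN (-0.67) and MCAM (-0.60) lower. Camera called none of these 3 lists at 24 h (adjusted p = 0.14, 0.908 and 0.547).

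Other lists fixed in advance had these higher and lower counts at 24 h, over all genes tested, with no call by camera. Circadian genes had 3 and 7 of 18 (3 and 7 adjusted over the list alone), with NR1D2 (LFC -0.98) and CIART (-1.19) lower and DBP (1.05) higher. Of 19 interferon genes 3 rose, STAT2 (LFC 0.53) and ISG15 (0.36) among them, and 1 fell (3 and 0 adjusted over the list alone). The metal and oxidative stress list had 3 and 5 of 14 (3 and 5 adjusted over the list alone), with the metallothionein gene MT2A at 57.8 ± 8.26 CPM from 195 ± 19.1. The chaperone list had 1 and 4 of 13 (2 and 4 adjusted over the list alone), the endoplasmic reticulum stress list 2 and 4 of 19 (2 and 4), the p53 list 3 and 4 of 20 (4 and 6), the G2/M list 4 and 6 of 36 (6 and 6), the glucocorticoid list 3 and 5 of 11 (3 and 5) and the Notch pathway component list 2 and 5 of 32 (2 and 5). The balance depended on scaling in the G2/M list (11 and 2 with library sizes only, 8 and 5 with DESeq2 size factors) and in the endoplasmic reticulum stress list (4 and 2 with library sizes only). Epithelial genes had 3 and 2 of 7 (3 and 2), with KRT18 at 1410 ± 95.2 CPM from 358 ± 6.08, and replication histones 0 and 0 of 29 (0 and 0). Of the marker lists of other cell types, those of neurons, microglia and endothelium were low in mock washout, with TUBB3 (5.43 CPM), CSF1R (2.23 CPM) and TIE1 (4.40 CPM) highest, and those of oligodendrocytes and epithelium had 3 and 2 members above 10 CPM, with CSPG4 (451 CPM) and KRT18 (358 CPM) highest. Endothelial genes had 1 and 2 of 6 (1 and 3), oligodendrocyte genes 2 and 1 of 5 (2 and 1), and among lists too small to test the neuron list had 0 and 2 of 4 (0 and 2), the microglia list 1 and 0 of 1 (1 and 0) and the RNA quality list 0 and 1 of 4 (0 and 3). The 2 oligodendrocyte genes higher, MBP and CNP, were not called without mock replicate 2 (adjusted p = 0.0602 and 0.101) or without 24 h replicate 2 (0.136 and 0.055). The mitochondrially encoded list has 0 measured members.

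Protein-coding genes changed at 4 h, higher or lower, often lay near one another. Of 909 genes higher at 4 h, 136 had another whose start lay within 100 kb of theirs, without overlap, against 71.5 in sets matched on expression and local gene density (95% 51 to 92; permutation p = 1e-04, the smallest that 10000 sets can give; adjusted p = 4e-04 over 16 tests), which argues against chance placement. The test was first run with a minimum distance on divergent pairs only, and the minimum of 1 kb was then applied to all pairs; with it, 128 genes against 67.4 had such a neighbour (permutation p = 1e-04). Read-through from 1 gene of a divergent pair cannot reach the other, as the genes start away from each other. Yet 46 genes lay in such divergent pairs against 26.3 (14 to 41, permutation p = 0.0059, adjusted p = 0.0189). With the minimum, 38 did against 21.9 (permutation p = 0.015, adjusted p = 0.034). Read-through between the genes of a pair thus does not account for this excess. Pairs were not limited to adjacent genes, so read-through from another changed gene nearby was not excluded. Genes lower at 4 h showed a like excess, 84 of 616 against 42.1 (permutation p = 1e-04, adjusted p = 4e-04). Placement near one another was thus not limited to induced genes. The divergent pairs of genes lower at 4 h did not pass after adjustment, 25 genes against 14.4 (permutation p = 0.035, adjusted p = 0.0509), and did with the minimum, 23 against 12.4 (permutation p = 0.027, adjusted p = 0.0448). Genes higher at 2 h had 14 of 284 against 5.6 (permutation p = 0.017, adjusted p = 0.034), with 4 in divergent pairs against 2 (permutation p = 0.26). At 24 h the outcome depended on the minimum: 716 genes against 674.3 without it (permutation p = 0.028, adjusted p = 0.0448) and 686 against 652.9 with it (permutation p = 0.066, adjusted p = 0.0812). Shared regulatory elements are a candidate explanation that was not tested.

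Pairs of protein-coding neighbours by this measure that both rose at least 2-fold at 4 h, named after their values were seen, were GUCY1A1 and GUCY1B1 on chromosome 4 (LFC 3.72 and 4.10), KRT3 and KRT79 on chromosome 12 (6.03 and 3.40), OLFM2 and COL5A3 on chromosome 19 (2.46 and 4.44), and MYLK2 and FOXS1 on chromosome 20 (1.51 and 4.86). PERM1 and HES4, COL6A3 and MLPH, and HRCT1 and SPAAR were the others. Of these pairs only COL6A3 and MLPH start away from each other. MYLK2 and FOXS1 lie on opposite strands facing each other, and in every other pair both genes lie on the same strand. For all pairs but COL6A3 and MLPH, read-through from 1 gene into the other is therefore not excluded. SLC6A12 and IQSEC3, whose starts lie more than 100 kb apart, are not counted as neighbours. The microRNA cluster of chromosome 14 had 19 measured members with a median LFC of 0.17 at 2 h (1 called higher, 0 lower), -1.17 at 4 h (0 and 5) and -0.69 at 24 h (1 and 1), at a median of 10.1 counts per library. The long noncoding RNAs of the same locus, MEG3, MEG8 and MEG9, fell at 4 h (LFC -0.40, -0.38 and -0.93) and stood at -0.63, -0.57 and -0.87 at 24 h, all called. Whether the counts at the microRNA genes come from microRNAs or from longer transcripts across the locus was not tested.

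Other splits of the libraries tested how far the counts could arise from any grouping. For genes changed at any time, 1 of 50 splits of the 12 libraries, the real one, gave as many as 7534. The highest of the others gave 38, so a random grouping of these libraries is unlikely to give the count. Since the libraries of a group may not be separate cultures, the splits cannot exclude differences between cultures that are unrelated to the washout. For each contrast of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and highest other counts, fitted on those 6 libraries, were 291 and 0 genes at 2 h, 1506 and 22 at 4 h, 5344 and 0 at 24 h, 899 and 56 between 2 and 4 h, and 7656 and 0 between 4 and 24 h. For list calls they were 12 and 11 at 2 h, 11 and 9 at 4 h, and 11 and 8 at 24 h.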
